A study of Glycine max with 18 samples.

How the data were processed

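Messenger RNA was sequenced from soybean (Glycine max), all of 1 cultivar. The labels describe 18 libraries, 3 biological replicates at each of 6 stages. Embryos of the cotyledon stage came from seeds 2.5 to 3.5 mm long and early maturation embryos from seeds 6 to 7 mm long. Mid maturation embryos came from seeds that weighed 200 to 250 mg and late maturation embryos from completely yellow seeds of 230 to 500 mg. Mature dry seed and seedlings taken 8 days after sowing completed the series. The labels name whole seedlings, while the seedling columns carry a heading with the letters COT. The labels were followed. Per the labels' protocols, polyadenylated RNA was selected and the libraries carried barcoded adapters.

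Each deposited file held 1 normalized signal value for each of 51546 gene identifiers. The submitters' processing notes name Bowtie 0.12.7, a read aligner, and edgeR 3.0.8, a package for count data. The genome build, the annotation, the counting and the treatment of reads that match more than 1 gene are not given in the sources used here. Soybean carries many near-identical gene pairs, so the value of a single gene is uncertain where reads could belong to either copy.

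The deposited signal values of a library were whole multiples of 1 step, which is the value of 1 read. Dividing by that step returned numbers within 0.05 of a whole read for 927826 of 927828 values. The scaling implied by the steps matched trimmed mean of M-values (TMM) factors recomputed from the recovered reads to a relative difference of at most 1.61e-07. The values are therefore described as CPM with TMM scaling. Recovered reads ranged from 3572134 to 8776240 per library, and 3 reads, taken as the floor for a gene without reads, corresponded to values between 0.263 and 1.30. Floors cover counting error only, since PCR copies are not independent molecules.

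The gene table at hand (Glycine max v4.0, 59048 genes) paired 0 of the 51546 identifiers with a name. The files do not pair them either. Gene lists fixed before the data were examined could therefore not be tested, and no gene is named by function. In each comparison at most 2 identifiers that rose and 2 that fell are given. They have the largest and the smallest log2 difference among called genes with a mean of at least 50 in the higher stage and with no overlap between the replicates of both stages.

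The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), two-sided, with a mean-variance trend and 1 model over the 18 libraries. It covered the 36872 genes with a value of at least 1 in at least 3 libraries. Each stage was compared with the stage before it. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. Log2 differences on this scale understate the change of genes with low values. The moderated F test of limma served for differences among the 6 stages, with the same adjusted p and a log2 range of at least 1 between the highest and the lowest stage mean. This design, the stage comparisons and all alternatives except thinning were fixed before the data were examined.

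The procedure was tested on simulated counts for each comparison. In the simulated comparison of early maturation with cotyledon, 63 of 67 genes changed 4-fold and 66 of 66 changed 8-fold were called in the right direction among 36872 genes. Of 67 genes changed 2-fold, 17 were called and 41 passed the adjusted p alone, and 0 of 36672 unchanged genes were called. In the simulated comparison of dry seed with late maturation, 64 of 67 genes changed 4-fold were called, and 7 of 36672 unchanged genes. The most unchanged genes called were 11, in late against mid maturation. Few genes were changed in the simulation, balanced between directions, whereas the real steps called 18.7% to 61.5% of genes. It therefore does not cover errors of scaling that arise when many genes change.

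Alternatives covered the pseudocount, the filter, the scaling, the replicate number as a block, the libraries in the fit, the limit on the difference, the trend, each library left out in turn, and count models on the recovered reads (edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0). Thinning every library to 3572134 reads was added after seeing the data.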

Results

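The series followed soybean gene expression through embryo and seed maturation, the dry seed and the young seedling. It comprised 18 libraries, 3 biological replicates at each of 6 stages, in the order cotyledon stage, early, mid and late maturation, dry seed and seedling 8 days after sowing. Recovered reads per library ranged from 5010245 to 7931127 at the cotyledon stage, 5122702 to 8776240 in early, 3572134 to 7097840 in mid and 3843336 to 6615868 in late maturation. They ranged from 4051230 to 4942973 in dry seed and from 5195421 to 8472161 in seedlings. Values below are CPM with TMM scaling, and genes carry the identifiers of the files.

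Replicates lay close together. Pearson's r across 36872 genes, which are not independent of one another, was 0.974 to 0.990 within stages. Between neighbouring stages the mean r was 0.887 for cotyledon and early maturation, 0.852 for early and mid maturation, 0.730 for mid and late maturation, 0.915 for late maturation and dry seed, and 0.4997 for dry seed and seedling. The first principal component held 51.1% of the variance and ran from cotyledon and early maturation to dry seed. The second held 27.6% and set the seedlings apart from the seed stages. Late maturation replicate 1 stood apart from the others of its stage, at 165 on the first component against 193 and 208. No replicate pair agreed within counting noise (chi-square per degree of freedom of 1.49 or more), so none was treated as a library deposited more than once.

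**Figure D1:**
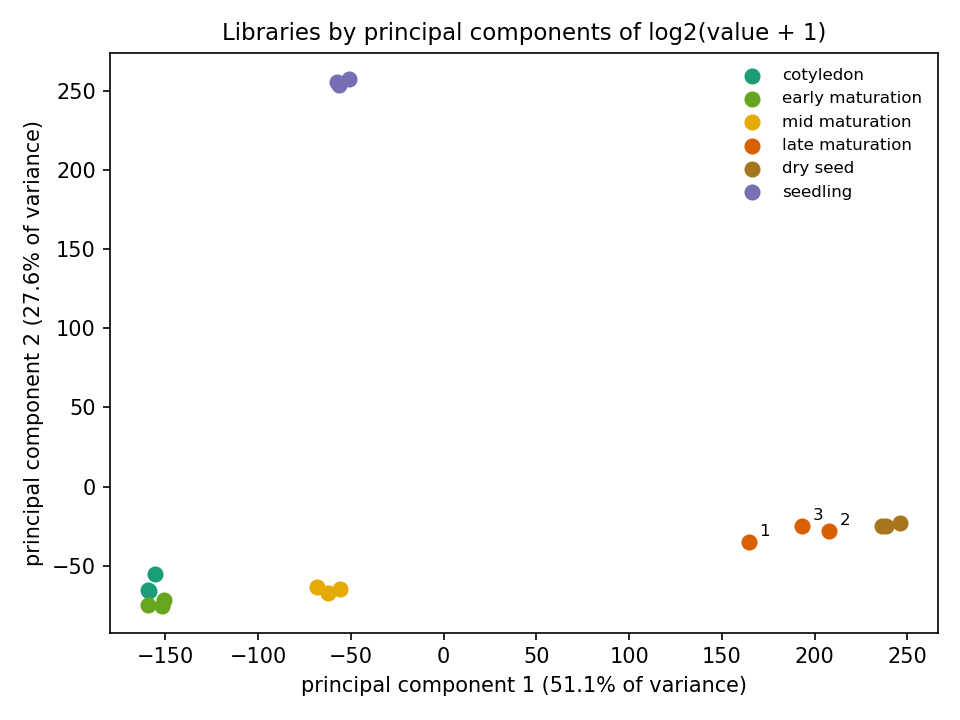
Principal components 1 and 2 of log2(value + 1) over 36872 genes, 1 point per library, coloured by stage, with replicate numbers shown for late maturation. The 3 seedling libraries lie between 253.7 and 257 on component 2, while no seed library exceeds -22.8.

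The number of genes detected was highest in seedlings and lowest in dry seed. Genes with a value of at least 1 numbered 28968 ± 381 (SD, n = 3) at the cotyledon stage, 28973 ± 41.9 in early maturation and 28742 ± 214 in mid maturation. It was 25559 ± 618 in late maturation and 23783 ± 327 in dry seed, and 33355 ± 308 in seedlings. No test was run on these numbers. By the F test of limma, 34788 genes, 94.3% of those tested, differed among the 6 stages. The highest stage mean lay in seedling for 9716 of them, in dry seed for 5926, in cotyledon for 5757, in early maturation for 5525, in late maturation for 4228 and in mid maturation for 3636. Genes at 10 or more in every library of 1 stage and below 1 in every other library numbered 547 in seedlings. They numbered 5 at the cotyledon stage, 4 in dry seed, 3 each in early and mid maturation and 1 in late maturation. These counts depend on which stages were sampled. Neighbouring seed stages had similar profiles (mean r 0.730 to 0.915), whereas seedlings had no close neighbour (mean r 0.4997 to 0.535).

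The transcript pool was concentrated in few genes at mid maturation. Pool here means the reads of a library, with no correction for transcript length, so shares and ranks are not those of molecules. The 10 most abundant genes held 40.1% ± 0.439 of the mid maturation pool (SD, n = 3), against 3.71% ± 0.233 at the cotyledon stage, 8.31% ± 0.0851 in early maturation, 13.1% ± 1.16 in late maturation, 12.5% ± 0.499 in dry seed and 2.66% ± 0.0889 in seedlings. At mid maturation 21 to 24 genes made up 50% of the pool of a library, while 2742 to 2828 did so in seedlings and 2606 to 2813 at the cotyledon stage. The 100 most abundant genes of mid maturation, chosen on these libraries, held 58.6% ± 0.709 there, 17.4% ± 0.495 in early maturation, 3.65% ± 0.112 at the cotyledon stage and 2.01% ± 0.00582 in seedlings. Chosen on replicate 1 alone, such a group held 58.2% and 59.4% of the other mid maturation libraries. Since the groups were chosen on these libraries, calls of their members in steps to or from their own stage are not independent evidence of direction. The abundant genes of dry seed were largely those of late maturation, and less so those of mid maturation. Of its top 100, 71 were also in the top 100 of late maturation and 26 in that of mid maturation. As a group the top 100 of dry seed held 32.0% ± 0.505 of the mid maturation pool and 28.7% ± 0.902 of the late maturation pool. They held 30.02% ± 1.69 of the dry seed pool and 2.14% ± 0.0249 of the seedling pool. The share at mid maturation does not describe most members of the group. Of the 100 genes, 69 rose from mid to late maturation, and the median log2 difference of the group was 3.09.

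**Figure D2:**
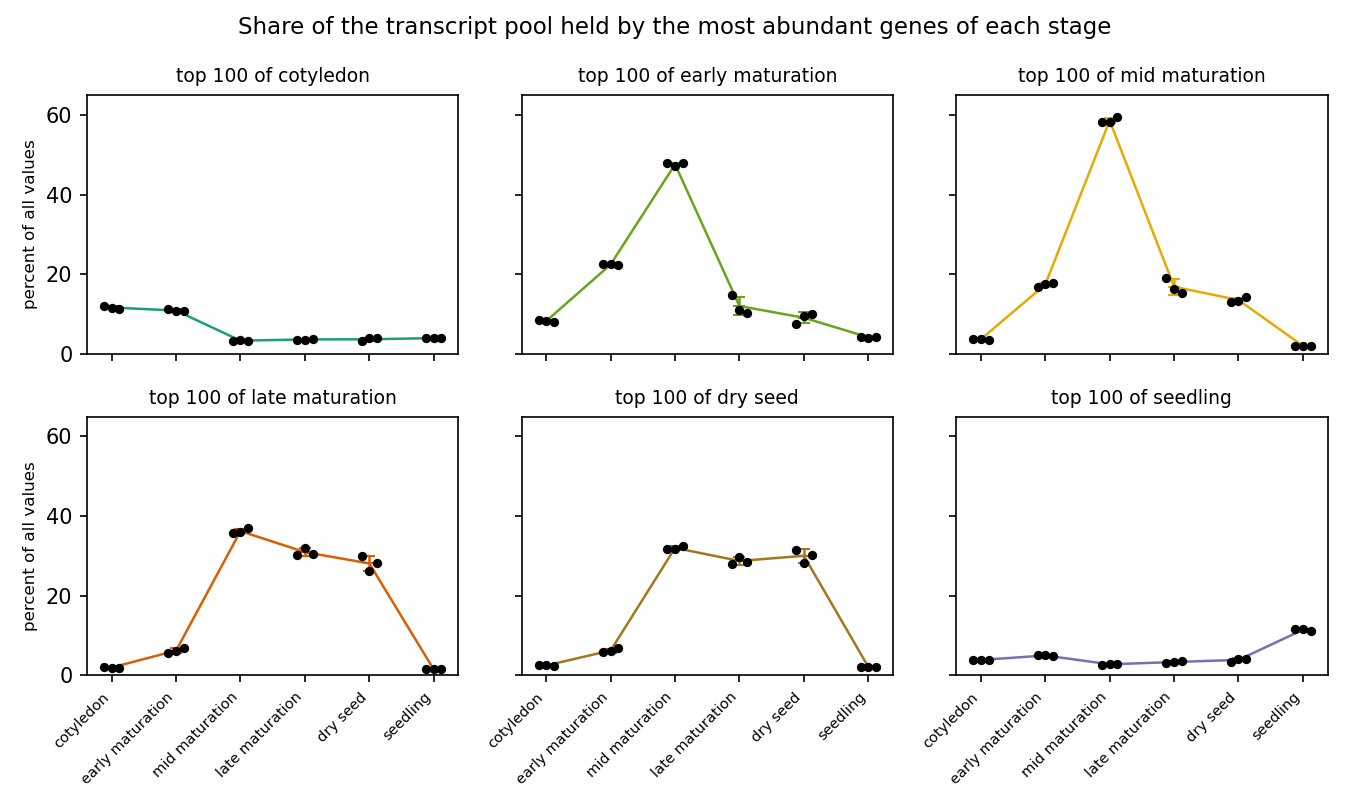
Percent of all values in a library held by the 100 most abundant genes of each stage, 1 panel per group of genes. Black points are libraries, the line joins stage means and bars are SD (n = 3). The mid maturation group reaches 58.6% at its own stage and 2.01% in seedlings.

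From the cotyledon stage to early maturation 3145 genes rose and 3760 fell, 18.7% of those tested (limma). The most abundant genes of later seed filling were already among those that rose. Of the top 100 of mid maturation 78 rose, with a median log2 difference of 4.03. Of the genes that rose, 1200 had their highest mean in early maturation and 654 in mid maturation. Glyma.16G208900 rose from 3.11 ± 0.772 to 4534 ± 654 (SD, n = 3), a log2 difference of 10.12 (SE 0.392, limma adjusted p = 1.44e-14), and reached 17930 ± 2690 at mid maturation. Glyma.05G011200 rose from 0.306 ± 0.258 to 950 ± 373 and was at 1.41 ± 1.42 by mid maturation. Among those that fell, Glyma.U037700 went from 83.6 ± 5.39 to 1.56 ± 0.354. Glyma.09G131500 went from 205 ± 93.5 to 2.24 ± 0.967, and its mean was higher again in dry seed, at 730 ± 171. In cotyledon replicate 3, 40 genes restricted to seedlings (mean of at least 300 there and under 5% of it at every other stage) stood at a median of 0.628% of their seedling level, against 0.1004% and 0.1019% in the other cotyledon libraries. Without it 3151 genes rose and 3764 fell. The balance of directions depended on the scaling. With all libraries, 3399 rose and 3402 fell after upper-quartile rescaling, and 3130 and 3676 after median-of-ratios rescaling.

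Between early and mid maturation 4181 genes rose and 5402 fell, 25.99% of those tested (limma). Of the top 100 of mid maturation, a group chosen on libraries of this step, 65 rose and 4 fell. Of the top 100 of the cotyledon stage, chosen on other libraries, 3 rose and 53 fell. Of the genes that rose, 1507 had their highest mean at mid maturation and 1203 in late maturation. Glyma.03G239700 rose from 25.9 ± 16.3 to 10953 ± 681 (SD, n = 3), a log2 difference of 8.96 (SE 0.444, limma adjusted p = 1.08e-12). Glyma.20G148200 rose from 0.168 ± 0.0564 to 555 ± 75.6, with 4 reads in all early maturation libraries together. Glyma.05G011200, which had risen in the preceding step, fell by 8.70 on the log2 scale (SE 0.331). Glyma.04G124100 fell from 1659 ± 182 to 3.58 ± 1.61. Early maturation replicate 3 correlated more closely with mid maturation (r across genes 0.863 to 0.879) than the other early maturation libraries did (0.827 to 0.853), and also with the cotyledon stage (0.9000 to 0.906, against 0.875 to 0.885). The same held with every late maturation, dry seed and seedling library, so the difference was not particular to the neighbouring stages. Without early maturation replicate 3, 4625 genes rose and 5815 fell. With all libraries, 4581 rose and 4948 fell after upper-quartile rescaling, and 4300 and 5145 after median-of-ratios rescaling.

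Late maturation differed from mid maturation by more genes than any earlier step, with 6191 that rose and 8715 that fell, 40.4% of those tested (limma). Changes were also larger, since 855 of the genes that rose and 1464 of those that fell did so by a log2 difference of 3 or more. Of the top 100 of mid maturation, a group chosen on libraries of this step, 66 fell, with a median log2 difference of -2.84. Of the top 100 of dry seed, chosen on other libraries, 69 rose, with a median of 3.09. The summed share of that dry seed group was nevertheless not higher in late maturation (28.7%) than in mid maturation (32.0%). Of the genes that rose, 2765 had their highest mean in dry seed and 2332 in late maturation. Glyma.06G283900 rose from 14.7 ± 5.75 to 12250 ± 4607 (SD, n = 3), a log2 difference of 9.61 (SE 0.288, limma adjusted p = 8.42e-17). Glyma.13G278000 rose from 0.789 ± 0.686 to 961 ± 221 and was at 1270 ± 141 in dry seed. Glyma.13G035200 fell from 8476 ± 607 to 8.12 ± 3.86, and Glyma.08G341000 from 2169 ± 397 to 2.79 ± 1.22. Without late maturation replicate 1, 6434 genes rose and 9025 fell.

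Dry seed lay close to late maturation. In this step 2891 genes rose and 5337 fell, 22.3% of those tested (limma), and 88 and 125 of them did so by a log2 difference of 3 or more. Of the top 100 of late maturation 73 were not called. Of the genes that rose, 2081 (72.0%) had their highest mean in dry seed. Glyma.18G050600 rose from 7.78 ± 1.24 to 543 ± 77.3 (SD, n = 3), a log2 difference of 5.95 (SE 0.240, limma adjusted p = 1.79e-13), and Glyma.05G092300 from 3.31 ± 0.984 to 205 ± 28.4. Glyma.06G295700 fell from 104 ± 8.20 to 2.52 ± 0.722 and was at 306 ± 18.8 in seedlings, while Glyma.13G051900 fell from 58.0 ± 16.7 to 1.17 ± 0.379. The labels give embryo as the tissue of late maturation and seed as that of dry seed. The protocol mentions the seed coat beside the embryo for late maturation, and the labels do not state whether the coat of dry seed was kept, so whether tissue changed with stage is open. The balance of directions depended on the scaling. Genes that rose made up 35.1% of calls as reported and 46.7% after median-of-ratios rescaling, with 3809 that rose and 4350 that fell. DESeq2 on the recovered reads called 4562 that rose and 5882 that fell. Without late maturation replicate 1, 2628 genes rose and 5170 fell, and 7141 of the 8228 calls were made again. Without late maturation replicate 2, 3230 rose and 5544 fell. Dry seed replicate 1 differed most within its stage (chi-square per degree of freedom 8.65 and 7.67, against 2.03 for the other pair). Without dry seed replicate 1, 2829 genes rose and 5232 fell.

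Seedlings differed from dry seed by more genes than any other neighbouring stages, with 15403 that rose and 7284 that fell, 61.5% of those tested (limma). The difference was 3 or more on the log2 scale for 4303 of those that rose and 1130 of those that fell. The abundant seed transcripts were among the genes that fell. Of the top 100 of dry seed 96 fell and 0 rose, with a median log2 difference of -6.91, and of the top 100 of late maturation 97 fell and 0 rose. Of the top 100 of seedlings 79 rose. The dry seed and seedling groups were chosen on libraries of this step, so their calls are not independent evidence of direction. The late maturation group was chosen on other libraries. Of the genes that rose, 8629 had their highest mean in seedlings and 2672 at the cotyledon stage. Glyma.09G038600 rose from 1.08 ± 0.489 to 1522 ± 119 (SD, n = 3), a log2 difference of 9.54 (SE 0.394, limma adjusted p = 2.21e-15), and Glyma.08G193500 from 0.572 ± 0.339 to 1087 ± 86.7. Glyma.17G040800 fell from 13685 ± 4329 to 13.3 ± 10.6, and Glyma.13G119400 from 8132 ± 3479 to 7.58 ± 5.37. The labels give seed and seedling as the tissues, so tissue and stage changed together.

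**Figure D3:**
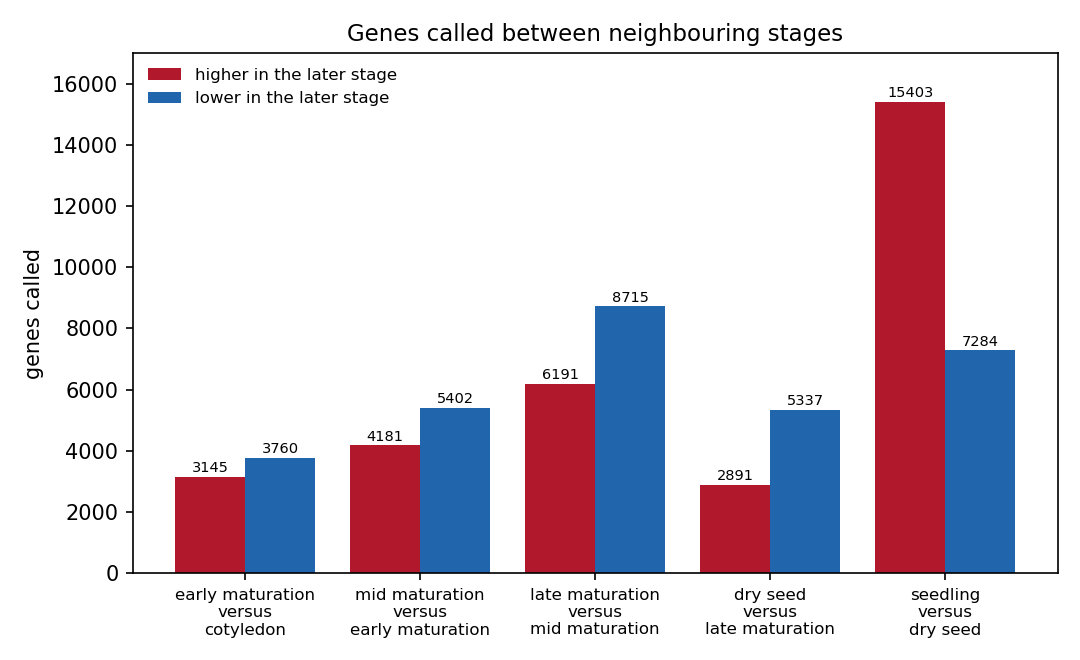
Number of genes called higher (red) or lower (blue) in the later of 2 neighbouring stages, at adjusted p under 0.05 and a log2 difference of at least 1, from 3 libraries per stage. The step from dry seed to seedling has 15403 genes higher, and that from late maturation to dry seed 2891.

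Whether genes that fell during maturation rose again in the seedling was examined from comparisons that share no library. Of the 5402 genes that fell from early to mid maturation, 2788 (51.6%) rose from dry seed to seedling, where independent lists would share 2257. Those that fell in both steps numbered 576, against 1067 for independent lists. Of those that rose from early to mid maturation, 1183 fell from dry seed to seedling (826 for independent lists) and 1338 rose (1747 for independent lists). Counts for the step from mid to late maturation lay further from those of independent lists. Of the 8715 genes that fell in it, 6148 (70.5%) rose in seedlings and 247 fell, against 3641 and 1722 for independent lists. Of the 6191 genes that rose in it, 3458 (55.9%) fell in seedlings, against 1223 for independent lists. No p-value is given, since genes are not independent. Sharing no library does not make the steps independent either. Late maturation and dry seed had similar profiles (mean r 0.915), mid maturation and dry seed less so (0.632). A gene low at the end of the first step was thus likely low in dry seed, with little room to fall again. How much of the departures from independent lists comes from this was not tested.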

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

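Of 371 counts of called genes recomputed under 31 alternative settings, 352 stayed within 1.5 times the reported count. The 19 others came from a pseudocount of 4, from dropping the limit on the difference, and from DESeq2. Of the 31 settings, 18 left out 1 library, which hardly alters comparisons of other stages, so many of the 371 counts could barely move. With a pseudocount of 4, which shrinks differences of genes with low values, 1817 genes were higher and 2167 lower in early maturation than in cotyledon, 2570 higher and 3307 lower in mid than in early maturation, 5091 lower in late than in mid maturation, 1780 higher and 2551 lower in dry seed than in late maturation, and 9695 higher in seedling than in dry seed. The overlap of genes that fell from early to mid maturation and rose in seedlings was then 1293. With no limit on the difference, a looser criterion by construction, the counts were 8330 and 8556 for early maturation, 8929 and 11376 for mid maturation, 10779 and 13958 for late maturation and 7144 and 10929 for dry seed, higher first, and the overlap was 6411. That overlap was only 1.06 times the count of independent lists, against 1.24 times as reported. DESeq2 called 4562 genes higher in dry seed than in late maturation, and the cause was not tested. edgeR on the recovered reads called 3529 higher and 7395 lower there, within 1.5 times the reported counts.

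The numbers of detected genes moved with the minimum value. In stage order they were 31640, 32123, 31127, 28396, 26766 and 36669 at a value of at least 0.5, and 21322, 20967, 20159, 17930, 16266 and 22646 at a value of at least 5. With every library thinned to the shallowest, an alternative chosen after seeing the data, genes with at least 5 reads numbered 28428 in early, 25829 in mid and 24082 in late maturation and 22079 in dry seed. Dry seed was lowest and seedling highest of the 6 stages at both minimum values.

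Replicate numbers did not pair the libraries. Of 15 same-numbered pairs in neighbouring stages 2 had deviations correlated above 0.1 (range -0.154 to 0.110), and 8 of 18 libraries correlated best with a library of their own number. With the replicate number as a block, 3147 genes were higher and 3760 lower in early maturation than in cotyledon, and 15404 higher and 7284 lower in seedling than in dry seed. Leaving out each library in turn moved no count of called genes by over 1.5 times, although comparisons of other stages could hardly change. The 20 named entries kept their direction and call in all 619 values computed under other settings. They were chosen as the largest differences, far above the limit, so this says little about other genes. Gene list tests, with either inter-gene correlation, were not run, and the fit to the libraries of a single pair of stages gave no value for the test among 6 stages.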

Other observations

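The tests on abundant seedling-restricted genes in cotyledon replicate 3 and on genes restricted to mid maturation were chosen after their results were seen, while the other tests below were set before theirs. The patterns themselves were noticed in these data.

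The 3 late maturation libraries did not lie equally far from mid maturation. Replicate 1 correlated with the mid maturation libraries at 0.748 to 0.762 across genes, and the others at 0.703 to 0.729.

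Cotyledon replicate 3 held low levels of transcripts restricted to seedlings. Of 40 genes with a seedling mean of at least 300 and under 5% of it at every other stage, chosen without that library, 38 (95%) were higher there than in both other cotyledon libraries. Of 91 such genes with a seedling mean of 100 to 300, 81.3% were, against 33.3% by chance order. Seedling RNA or reads mixed into that library are a candidate explanation, at a median excess of 0.498% of the seedling level for the abundant genes. Single genes switched on in that sample would give unequal fractions. The upper quartile of the excess was 1.37 times the lower quartile for the abundant genes, which argues against that reading for them. For the less abundant genes it was 2.75 times, between the bounds set for either reading, so there it stays open.

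Genes abundant in dry seed also had reads in the cotyledon libraries. Of 162 genes with a dry seed mean of at least 200 and a mid maturation mean under 5% of it, 161 had at least 1 read at the cotyledon stage. Single cotyledon libraries had reads for 38512 to 41504 of all 51546 genes, so this count alone is no sign of carry-over. Between the lowest and the highest of 4 bins of dry seed level, the median dry seed level rose 15.9-fold and the 10th percentile of the cotyledon level 10.9-fold, a ratio of 0.683. That percentile was 0.0490% to 0.0802% of the dry seed level over the bins. A floor that follows the level in another stage is what reads or RNA carried between libraries would give. A carry-over at 1 share from every stage is argued against as the source of the whole floor, but not as a part of it. The dry seed genes were required to be low only at mid maturation, so their cotyledon reads can include transcription in embryos. Counted in reads, the 10th percentile was 0.0904% to 0.146% of the dry seed reads over the bins, whereas the 7 genes restricted to mid maturation stood in the cotyledon libraries at a median of 0.0359% of their mid maturation reads, with an upper quartile of 0.0438% and a highest value of 1.147%. For genes restricted to seedlings the 10th percentile was also low, at 0.0121% and 0.0141% of the seedling level in cotyledon replicates 1 and 2. Carry-over from dry seed libraries in particular and low transcription in embryos cannot be told apart, since no value here separates them.

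The excess of genes that fell from early to mid maturation and rose again in seedlings was weighed against 2 technical explanations. Within 10 bins of mean expression the observed count was 1.31 times that of independent lists, which argues against expression level as the whole cause, although the ratio was 0.151 in the lowest bin and 1.93 in the highest. Under the other scalings the lower ratio was 1.24, so the excess did not depend on the choice among the scalings tried. A scaling error common to all of them, as can arise when many genes change, is not covered. The size of the excess depended on the limit on the difference. With no limit the ratio was 1.06, against 1.24 as reported and 1.49 with a pseudocount of 4. Whether genes low at mid maturation and still low in dry seed produced the excess was not tested, nor was any biological explanation.

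For the number of genes that differed among stages, a random grouping of the libraries is argued against as the source of the total. This says nothing about any single gene. The real grouping gave the highest count among 100 groupings of the 18 libraries (1 of 100 as large), with 34788 genes that differed among stages against at most 7180. For comparisons of neighbouring stages the 10 splits of 6 libraries are too few for a share under 0.05, and 1 split of 10, the real one, gave as many genes. The real value and the highest of the other splits were 6905 and 0 for early maturation against cotyledon, 9583 and 1 for mid against early maturation, 14906 and 8 for late against mid maturation, 8228 and 44 for dry seed against late maturation, and 22687 and 0 for seedling against dry seed. The overlap of genes that fell from early to mid maturation and rose in seedlings was 2788, against at most 1 among the other pairs of splits, but these called too few genes to overlap, so the splits say nothing about its excess.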
